A study of Mus musculus with 6 samples.

How the data were processed

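Splenic B cells were obtained by negative selection from male C57BL/6 mice 6 weeks old, activated with LPS (10 µg/ml) for 48 h and cultured with IFNα (100 U/ml) for 2 h or 8 h, per the series' labels. RNA was extracted with TRIzol, amplified with the Ambion WT Expression Kit and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. The labels call the control samples untreated with cytokine and name DMSO and CCM in their titles, and the preparation label of the IFNα samples mentions JAK inhibitors without saying whether any sample received one. All 6 arrays were used, in 3 groups of 2 (control 2 h, IFNα 2 h and IFNα 8 h), each with the replicate numbers 2 and 3. The labels name no control kept for 8 h.

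The deposited values are intensity values per probe set on a linear scale, from 12.5 to 24041. The submitters' processing notes name Affymetrix Power Tools and RMA, a method that summarises and normalizes probe intensity, with no version, role or order. The arrays as deposited differ in their quantiles, and the normalization step behind this is not stated. No genome build is stated, so no coordinates are given.

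From these values log2 intensity was computed with no offset. The platform's annotation named 1 gene for 21425 of the 24922 probe sets, several for 1399 and none for 2098. Only probe sets with 1 gene symbol were named, which gave 19752 genes, and for the 921 genes with more than 1 probe set the one with the highest mean over the 6 arrays was taken. Stat1, Isg15, Cd19, H2-K1, H2-D1, H2-T23 and Gbp2 are among the listed genes with no such probe set and are not analysed here. A gene was tested when it lay above the median of all values (log2 7.45, an intensity of 175) on at least 2 arrays, which kept 10533 genes and left out 9219. Where a group's mean lies below the level cut, the size of a difference is uncertain. The number of arrays limits the precision, and signal near the background limits what dim genes can show.

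The 3 comparisons were fitted with limma 3.58.1 (R 4.3.3) by lmFit and eBayes over all 6 arrays, with group means, no covariate and 3 residual degrees of freedom. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Of 27 lists with 467 symbols, 417 symbols were named on the array and 339 tested. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 27 lists within a comparison, with an estimated correlation and fry as alternatives. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Members were also counted after adjustment over the list alone. List medians are given relative to the median of all tested genes, because the scaling moved that median by over 0.1. Between comparisons that share controls, 100 draws of unchanged groups gave the values with no effect for genes that vary independently.

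The trend with signal level and gene span was removed as a further test, planned for 3 lists and reported for the others after results were seen: each array's deviations from the gene means were regressed on splines of both, the residuals took their place, and camera was run again on the 10529 genes with a known span.

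The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, in each comparison, the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold whose arrays did not overlap, the 2 members of each list with the smallest p, and always Stat1, Irf7, Irf9, Usp18, Socs1, Isg15, Myc and Cd19. For 6 lists of markers of other cell types it took the member with the highest mean.

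The alternatives were no filter and a stricter filter on level (log2 8.21, 7016 genes), a trended and robust variance, median centring, cyclic loess, the mean of a gene's probe sets, an offset of 32 before the log, a fold of at least 1.5, the replicate number as a block, a fit of only the 2 groups compared, and leaving out each array in turn. A group left with 1 array is then assumed to vary like the other groups. Quantile normalization, the interquartile range of each array as a covariate and a crossed pairing were chosen after the data were seen. The gene test and camera were tested on simulated data with the spread of these arrays: 66 or 67 genes were changed by each of 3 known amounts, with 10 to 13 false calls per comparison. In the camera test the shifted list of 27 passed (adjusted p = 8.21e-10) and 0 others passed. The simulated genes varied independently, whereas the estimated correlation within the shifted list, G2/M, was 0.55 in the real data. The simulation therefore does not show how camera performs with correlated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.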

Results

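Gene expression was measured on 6 microarrays of mouse splenic B cells that had first been activated with the bacterial lipopolysaccharide LPS and were then exposed to interferon alpha (IFNα), a type I interferon that induces antiviral genes. There were 3 groups of 2 arrays, each with replicates 2 and 3: a 2 h control without IFNα, 2 h of IFNα and 8 h of IFNα. The arrays held 24922 probe sets, of which 21425 named a single gene, and 10533 genes were bright enough to be tested. Median log2 intensity per array ran from 7.32 to 7.58. The spread of the signal differed between arrays: the interquartile range on the log2 scale was 1.80 on IFNα 2 h replicate 3 and 2.45 on IFNα 2 h replicate 2, and lay between 2.02 and 2.73 on the other 4 arrays. With 2 arrays per group, their number limits the precision, and the p-values describe only the spread between these arrays, since the labels do not say that replicates came from separate mice.

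**Figure D1:**
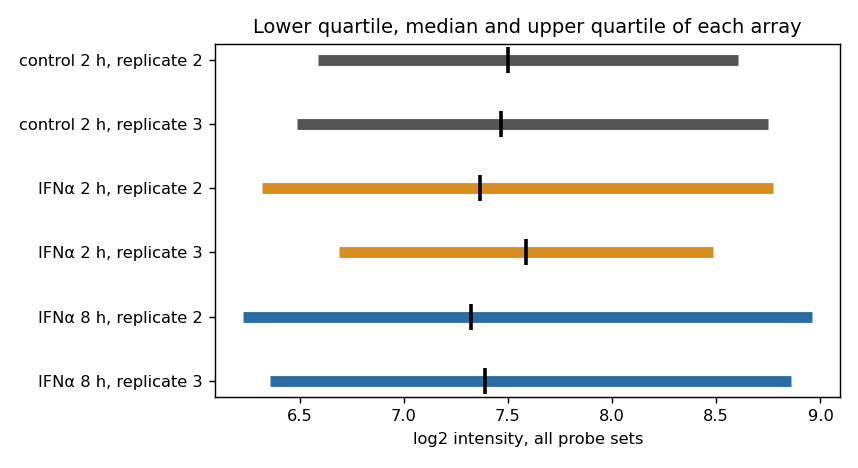
Lower quartile to upper quartile (bar) and median (black line) of the log2 intensity of all probe sets on each of the 6 arrays, coloured by group. IFNα 2 h replicate 3 has the narrowest bar, with an interquartile range of 1.80, and IFNα 8 h replicate 2 the widest, with 2.73.

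The first comparison, 2 h of IFNα against the 2 h control, asks which genes respond early to the interferon. The titles of the controls name DMSO and CCM and those of the IFNα samples do not, so differences from the control may also hold these. Rtp4, Ifi214 and Ifi208 rose, and no gene fell past the threshold. Rtp4, an interferon-induced receptor transporter protein (probe set 10434778), went from a mean log2 intensity of 6.78 ± 0.0071 (SD, n = 2) to 9.55 ± 0.06 (SD, n = 2). Its log2 difference was 2.77 ± 0.18 (SE), with a limma adjusted p of 0.00794. Ifi214 (probe set 10360370) had a log2 difference of 2.74 ± 0.27 and a limma adjusted p of 0.0439. Ifi208 (probe set 10351880) had 2.12 ± 0.19 and a limma adjusted p of 0.0288. The control means of all 3 genes lay below the level cut used for testing (log2 7.45), and those of Ifi214 (6.46) and Ifi208 (5.89) also below the lower quartile of both control arrays (6.49 and 6.59). The control signal is not shown to stand above background there, so no folds are given and the size of these rises is uncertain. Ifi208 and Ifi214 belong to a family of interferon-inducible proteins that bind DNA, whose near-identical members can share probes, so which member was measured is uncertain.

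The list of antiviral effectors rose as a group at 2 h, by a median of 0.47 on the log2 scale above all genes tested (camera adjusted p = 7.04e-11, and adjusted p = 0.896 with an estimated correlation). Of its 23 tested members 19 had a positive difference, 1 rose over all genes and 8 rose when adjusted over the list alone. Mx1, an antiviral GTPase, had a log2 difference of 2.00 ± 0.26 (adjusted p = 0.0907), with a control mean of 6.15 that lay below the lower quartile of both control arrays, so its size is uncertain. Some genes of other lists were higher on both IFNα arrays than on both controls without passing the test. Over all genes tested the arrays of the 2 groups did not overlap, in either direction, for 29.7%, against 33.3% expected by chance. Non-overlap alone is thus no sign of a response. Usp18, a protease that removes ISG15 and dampens interferon signalling, had a log2 difference of 2.42 ± 0.32 (adjusted p = 0.0907), and Xaf1, a promoter of cell death, had 1.83 ± 0.24 (adjusted p = 0.0907). Their control means, 7.37 and 7.25, lay below the level cut, so the size of both differences is uncertain. The RNA sensor Tlr7 had 1.32 ± 0.20 (adjusted p = 0.167) and the GTPase Irgm1 had 1.84 ± 0.39 (adjusted p = 0.309). Irf7 and Irf9, transcription factors of the interferon response, had log2 differences of 0.29 ± 0.43 and 0.66 ± 0.36, with adjusted p of 0.942 and 0.654, and their arrays overlapped between the groups. Socs1, a feedback inhibitor of cytokine receptors, had 0.43 ± 0.21 (adjusted p = 0.608), and the growth regulator Myc had 0.55 ± 0.24 (adjusted p = 0.569).

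Cytokine and chemokine genes rose as a list at 2 h, by a median of 0.26 above all genes (camera adjusted p = 0.0216, and adjusted p = 0.896 with an estimated correlation). Of the 11 tested members none passed over all genes and 1 rose when adjusted over the list alone. Tnf had a log2 difference of 0.89 ± 0.34 (adjusted p = 0.512). Il6 had 1.41 ± 0.19 (adjusted p = 0.101), of uncertain size, since its control mean of 5.24 lay below the lower quartile of both control arrays. The list's adjusted p was 0.0984 without IFNα 2 h replicate 2 and 0.0538 without IFNα 2 h replicate 3. Removal of the trend with signal level and gene span from each array ended the call: the median against all genes went from 0.26 (SD over members 0.56) to 0.14 (SD 0.53), with an adjusted p of 0.12. Its median log2 difference, 0.21, was 0.07 without control replicate 2, 0.34 without control replicate 3 and 0.45 without IFNα 2 h replicate 3.

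Lists of B cell identity, major histocompatibility complex (MHC) class II presentation and mitosis lay below the other genes at 2 h, and these calls ended without IFNα 2 h replicate 3, the array with the narrow signal range. With the interquartile range of each array as a covariate, B cell identity and MHC class II stayed lower (adjusted p = 0.00106 and 0.0127), as they did after quantile normalization (0.00148 and 0.0167), and G2/M no longer passed (0.06). B cell identity and receptor signalling genes lay lower by a median log2 difference of −0.32 against all genes (camera adjusted p = 0.00624, and adjusted p = 0.985 with an estimated correlation), with 18 of 19 members negative. Their median log2 difference, −0.37, was −0.08 without IFNα 2 h replicate 3, with an adjusted p of 0.281, −0.65 without IFNα 2 h replicate 2 and −0.18 without control replicate 3. Ebf1, a transcription factor of the B lineage, had −0.95 ± 0.34 (adjusted p = 0.488), and Fcrla had −0.64 ± 0.23 (adjusted p = 0.488). MHC class II presentation genes lay lower by −0.49 against all genes (camera adjusted p = 0.0272, and adjusted p = 0.985 with an estimated correlation), with 10 of 11 members negative. The median of these class II genes, −0.54, was 0.0038 without IFNα 2 h replicate 3, with an adjusted p of 0.693, −0.89 without IFNα 2 h replicate 2 and −0.33 without control replicate 3, and the adjusted p was 0.0592 without control replicate 2. Ifi30, a thiol reductase of the lysosome, had −0.75 ± 0.20 (adjusted p = 0.41), and H2-DMa, which helps to load peptides, stood at 0.501 times the control level (adjusted p = 0.429). G2/M genes, active in mitosis, lay lower by −0.21 against all genes (camera adjusted p = 0.0333, and adjusted p = 0.985 with an estimated correlation), with 18 of 23 members negative. Mki67, a marker of dividing cells, had −0.77 ± 0.25 (adjusted p = 0.467), and Kif23, a motor protein of cell division, had −0.48 ± 0.21 (adjusted p = 0.56). The G2/M list's adjusted p was 0.49 without IFNα 2 h replicate 3, 0.107 without control replicate 3, 0.0519 without either IFNα 8 h array and 0.0521 after quantile normalization. Its median log2 difference, −0.26, was −0.06 without IFNα 2 h replicate 3, −0.46 without IFNα 2 h replicate 2, −0.44 without control replicate 2 and −0.17 without control replicate 3. In these 3 lists no member passed over all genes or when adjusted over the list alone. Removal of the trend with signal level and gene span ended all 3 calls, with adjusted p of 0.12 for B cell identity, 0.0769 for MHC class II and 0.2 for G2/M. The medians against all genes went from −0.32 (SD over members 0.31) to −0.09 (SD 0.31) for B cell identity and from −0.21 (SD 0.30) to −0.11 (SD 0.27) for G2/M. The mean of B cell identity shrank less than its median, from −0.35 to −0.22. The median of MHC class II shrank little, from −0.49 (SD 0.40) to −0.41 (SD 0.41). Antiviral effectors kept theirs (adjusted p = 5.5e-09), so 1 of the 5 lists that passed at 2 h remained, and ubiquitin, ISGylation and PARP genes passed then (adjusted p = 0.0109, against 0.0676 before).

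The 3 genes that rose at 2 h and the 0 that fell came from limma over 10533 genes and all 6 arrays, and 449 genes were higher and 487 lower at an unadjusted p under 0.05. On simulated changes with the same arrays' spread, the test recovered 50.7% of genes changed by 1 on the log2 scale and 100% of those changed by 2 or 3. That simulation changed 66 or 67 genes by each amount, which makes the adjustment easier than with few changed genes, so it does not show that every change of 2 was found here. Ifi213, chosen here after its values were seen, had a log2 difference of 3.31 ± 0.38 at 2 h with an adjusted p of 0.0638. The counts turned on single arrays. They were 0 higher and 0 lower without control replicate 2 or without control replicate 3, where 280 and 192 genes were higher and 510 and 35 lower at an unadjusted p under 0.05 and Rtp4 had an adjusted p of 0.114 and 0.394. They were 274 higher and 1517 lower without IFNα 2 h replicate 2, 498 higher and 51 lower without IFNα 2 h replicate 3, and 1 higher and 0 lower without either IFNα 8 h array, where Rtp4 remained and Ifi214 and Ifi208 had adjusted p of 0.0709 and 0.0748. Rtp4 was also the only gene left after median centring.

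The second comparison sets 8 h of IFNα against the 2 h control. The labels name no control kept for 8 h, so these differences also hold 6 more hours of culture. At 8 h 25 genes rose and 1 fell. Ifi214 rose by a log2 difference of 3.55 ± 0.27 (limma adjusted p = 0.00698), Rtp4 by 2.90 ± 0.18 (limma adjusted p = 0.00332) and Ifi208 by 2.87 ± 0.19 (limma adjusted p = 0.00332). Ifi213 (probe set 10360373), of the same family as Ifi208, was higher by 3.46 ± 0.38 on the log2 scale (limma adjusted p = 0.0254). Usp18 (probe set 10541307) rose from a mean log2 intensity of 7.37 ± 0.05 (SD, n = 2) to 10.32 ± 0.11 (SD, n = 2), with a limma adjusted p of 0.0254. Xaf1 (probe set 10378068) rose by a log2 difference of 2.58 ± 0.24 (limma adjusted p = 0.0149). Mt2, a metallothionein that binds metal ions (probe set 10574023), fell by 2.16 ± 0.30 on the log2 scale, from 11.94 ± 0.06 (SD, n = 2) to 9.78 ± 0.17 (SD, n = 2), with a limma adjusted p of 0.049. Mt2 did not pass limma with no filter (adjusted p = 0.0538), an offset of 32 (0.0545), cyclic loess (0.0672), quantile normalization (0.071) or median centring (0.119).

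Antiviral effectors rose together at 8 h, by a median of 1.08 above all genes (camera adjusted p = 4.95e-19, and adjusted p = 0.533 with an estimated correlation). This was the only list call that fry kept (adjusted p = 0.0373). Fry gave the antiviral effectors 0.204 at 2 h and 0.13 at 8 h against 2 h, and the 7 other lists called at 8 h from 0.0796 to 0.328. All 23 tested members had a positive difference, 6 rose over all genes and 21 rose when adjusted over the list alone. Mx1 had a log2 difference of 2.37 ± 0.26 (adjusted p = 0.0254). Ubiquitin, ISGylation and PARP genes, which modify proteins during the interferon response, rose by a median of 0.68 above all genes (camera adjusted p = 1.26e-08, and adjusted p = 0.697 with an estimated correlation). Of these 16 genes 1 rose over all genes and 13 rose when adjusted over the list alone. Parp14 was 3.01-fold higher (1.59 ± 0.22, adjusted p = 0.049), and Herc6, a ligase that attaches ISG15, had a log2 difference of 1.25 ± 0.22 (adjusted p = 0.0895). Nucleic acid sensors rose by a median of 0.45 above all genes (camera adjusted p = 1.03e-05, and adjusted p = 0.697 with an estimated correlation). Of their 11 members 1 rose over all genes and 5 rose when adjusted over the list alone. Tlr7 rose by 2.00 ± 0.20 on the log2 scale (adjusted p = 0.0233), and Ifi203 had a log2 difference of 1.51 ± 0.24 (adjusted p = 0.0746). The sensors' median log2 difference, 0.60, was 0.92 without control replicate 3. Interferon-inducible GTPases rose by a median of 0.63 above all genes (camera adjusted p = 0.000651, and adjusted p = 0.697 with an estimated correlation). Of their 6 members none passed over all genes and 4 rose when adjusted over the list alone, and Irgm1 had a log2 difference of 2.56 ± 0.39 (adjusted p = 0.0722).

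Genes of interferon signalling and the interferon regulatory factors rose as a list at 8 h, by a median of 0.32 above all genes (camera adjusted p = 0.0127, and adjusted p = 0.846 with an estimated correlation). None of the 17 members passed over all genes and 3 rose when adjusted over the list alone. The list's adjusted p was 0.081 without control replicate 2 and 0.781 with the interquartile range of each array as a covariate. Irf7 had a log2 difference of 1.77 ± 0.43 (adjusted p = 0.179), Irf8 had 0.95 ± 0.22 (adjusted p = 0.171) and Irf9 had 1.03 ± 0.36 (adjusted p = 0.281). Socs1 had 0.12 ± 0.21 (adjusted p = 0.784). Cell death genes rose by a median of 0.37 above all genes (camera adjusted p = 0.00711, and adjusted p = 0.697 with an estimated correlation). Of these 17 genes 1, Xaf1, rose over all genes, and 5 rose and 1 fell when adjusted over the list alone. Casp1, the protease of the inflammasome, had a log2 difference of 1.08 ± 0.24 (adjusted p = 0.16).

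Cholesterol synthesis genes fell as a list at 8 h while G2/M genes rose. The median of the 14 cholesterol synthesis genes lay at −0.73 against all genes (camera adjusted p = 4.77e-08, and adjusted p = 0.697 with an estimated correlation), with 12 members negative, none past the threshold over all genes and 4 that fell when adjusted over the list alone. Lss, which makes lanosterol, had a log2 difference of −1.28 ± 0.35 (adjusted p = 0.218), and Fdps, an earlier enzyme of the pathway, had −0.98 ± 0.29 (adjusted p = 0.234). The G2/M genes rose by a median of 0.34 above all genes (camera adjusted p = 0.000258, and adjusted p = 0.738 with an estimated correlation). All 23 members had a positive difference, and none passed over all genes or when adjusted over the list alone. Cenpe, a motor protein of the centromere, had 1.08 ± 0.25 (adjusted p = 0.169) and Kif23 had 0.81 ± 0.21 (adjusted p = 0.19). The G2/M list's adjusted p was 0.0658 with the interquartile range of each array as a covariate.

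Beyond these lists, Il6 rose at 8 h from a control mean of 5.24 (log2 difference 2.30 ± 0.19, adjusted p = 0.00876), while the cytokine and chemokine list did not pass (median 0.25 above all genes, camera adjusted p = 0.388). Gpr183, an oxysterol receptor that positions B cells, rose 2.77-fold (1.47 ± 0.20, adjusted p = 0.049, and 0.0673 with the replicate number as a block). Myc had a log2 difference of 1.27 ± 0.24 (adjusted p = 0.112). The other 14 genes that rose were chosen after their values were seen. Ifi209 rose 5.11-fold and Oas2, an enzyme of the antiviral oligoadenylate pathway, 3.30-fold. Trim30d, Dcun1d5, Gpr174, Oasl2, Gm8995, Gm4759 and the small nucleolar RNA Snora75 rose between 2.89-fold and 4.19-fold. Slfn8, Ifit3, the double-stranded RNA-activated kinase Eif2ak2, Nmi and Slfn5 had log2 differences between 1.49 and 2.39. In all, 13 of the 25 genes that rose had a control mean below the level cut, and for Ifi208, Ifi214, Mx1, Il6 and Slfn5 it also lay below the lower quartile of both control arrays, so no folds are given for these 13 genes and the size of their rise is uncertain. Ifi209, Trim30d, Slfn8, Ifit3, Oas2, Oasl2, Gm8995 and Gm4759 have near-identical relatives, and their values are uncertain for that reason.

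**Figure D2:**
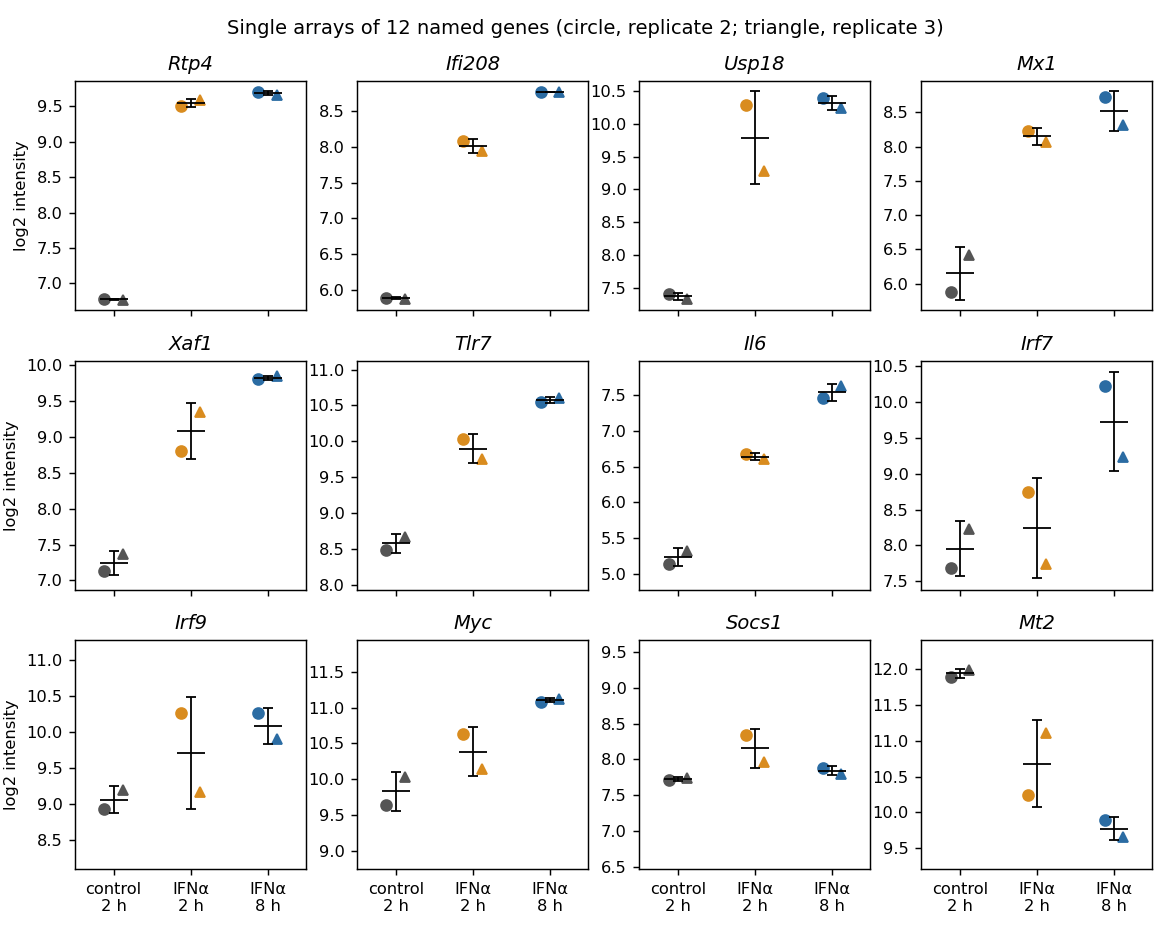
Log2 intensity of 12 named genes on single arrays (circle, replicate 2, and triangle, replicate 3), with the mean and SD of each group of 2 arrays in black. Rtp4 stands at a mean of 6.78 in the control, 9.55 at 2 h and 9.68 at 8 h of IFNα, and Usp18, Irf7 and Irf9 differ between the 2 arrays of IFNα 2 h.

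The 25 genes higher and 1 lower at 8 h came from limma over 10533 genes, with 1290 higher and 93 lower at an unadjusted p under 0.05. Of simulated changes, 32.8% of those of 1 and 100% of those of 2 or 3 on the log2 scale were recovered. As at 2 h, that simulation does not show that every change of 2 was found here. Irgm1, at a log2 difference of 2.56, did not pass (limma adjusted p = 0.0722). The tested genes together shifted at 8 h. Their median log2 difference from the control was 0.147 as deposited, 0.275 after median centring and 0.011 after quantile normalization. For 8 h against 2 h it was 0.202, 0.322 and 0.040. Over all probe sets the IFNα 8 h arrays had lower medians (7.32 and 7.39) than the controls (7.50 and 7.47). Their upper quartiles were higher (8.96 and 8.86, against 8.61 and 8.75), so the shift is not a rise of all genes. The counts were 6 higher and 0 lower after median centring (1474 and 29 at an unadjusted p under 0.05), 11 and 0 after quantile normalization (854 and 193) and 1228 and 105 with only the control and 8 h arrays. Without control replicate 2 or control replicate 3 they were 0 and 0, with 420 and 1013 genes higher and 37 and 49 lower at an unadjusted p under 0.05, and Rtp4 had an adjusted p of 0.166 and 0.171. Without IFNα 8 h replicate 2 or replicate 3 they were 3 and 0 (17 and 40 lower at an unadjusted p under 0.05), the 3 being Rtp4, Ifi208 and Ifi214, and without either IFNα 2 h array they were 1228 and 105.

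**Figure D3:**
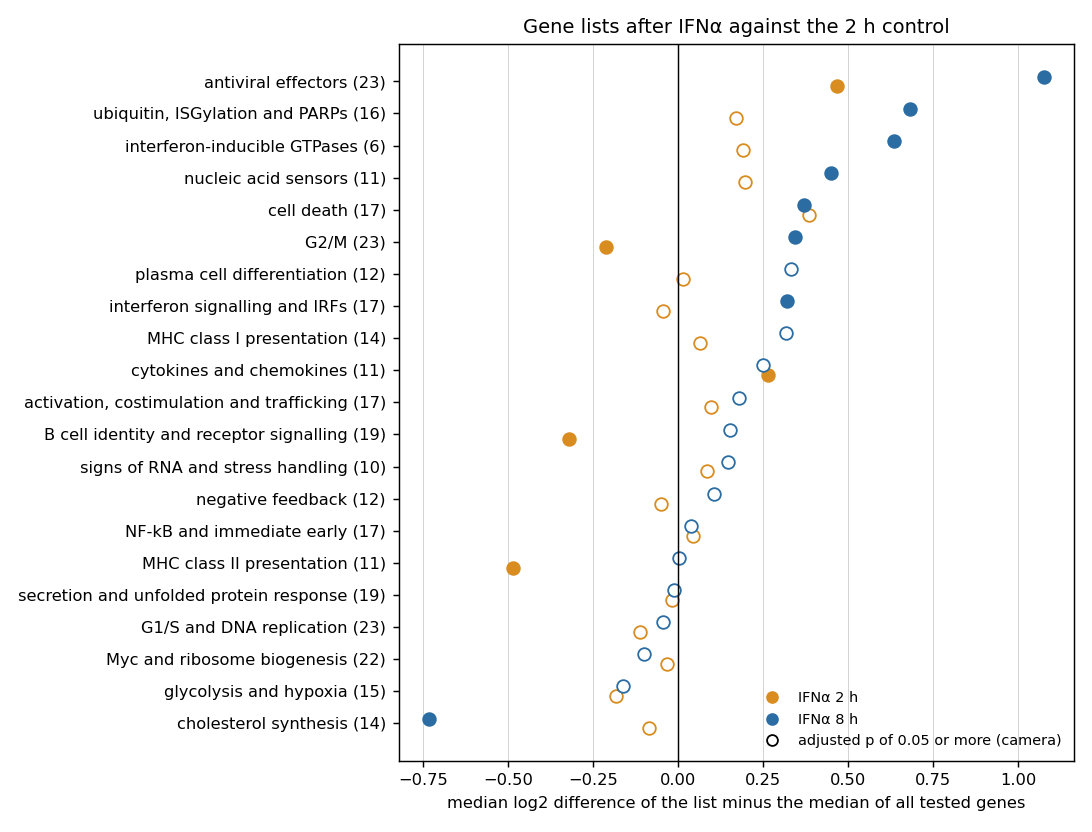
Median log2 difference of each of 21 gene lists minus the median of all tested genes, for 2 h (orange) and 8 h (blue) of IFNα against the 2 h control, with the number of tested members in brackets. Filled points passed camera at an adjusted p under 0.05. Antiviral effectors lie at 0.47 and 1.08, and cholesterol synthesis genes at −0.73 at 8 h.

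The third comparison sets 8 h against 2 h of IFNα without an 8 h control, so that time in culture and time with IFNα are mixed, and no single gene passed the threshold. Antiviral effectors lay higher at 8 h by a median of 0.55 above all genes (camera adjusted p = 0.000232, and adjusted p = 0.7 with an estimated correlation), with 21 of 23 members positive and 12 that rose when adjusted over the list alone. Their median log2 difference, 0.76, was 0.47 without IFNα 2 h replicate 3. Oas2 had a log2 difference of 1.34 ± 0.20 (adjusted p = 0.141), and Trim30a had 1.05 ± 0.19 (adjusted p = 0.141). Ubiquitin, ISGylation and PARP genes lay higher by 0.46 (camera adjusted p = 0.000215, and adjusted p = 0.7 with an estimated correlation), with all 16 positive and 10 that rose when adjusted over the list alone. Herc6 had 1.32 ± 0.22 (adjusted p = 0.141) and the ubiquitin ligase Rnf213 had 1.87 ± 0.33 (adjusted p = 0.141). Nucleic acid sensors lay higher by 0.47 (camera adjusted p = 0.000881, and adjusted p = 0.7 with an estimated correlation), with all 11 positive and 6 that rose when adjusted over the list alone. Usp18 had a log2 difference of 0.53 ± 0.32 (adjusted p = 0.341), and Rtp4, chosen here after its values were seen, had 0.13 ± 0.18 (adjusted p = 0.638).

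The G2/M genes were also higher at 8 h than at 2 h of IFNα, by a median of 0.49 above all genes (camera adjusted p = 7.31e-06, and adjusted p = 0.7 with an estimated correlation), with all 23 positive and 12 that rose when adjusted over the list alone. Their median log2 difference, 0.69, was 0.43 without IFNα 2 h replicate 3. Kif23 had 1.29 ± 0.21 (adjusted p = 0.141) and Cenpe had 1.33 ± 0.25 (adjusted p = 0.141). Cholesterol synthesis genes were lower, at −0.84 against all genes (camera adjusted p = 7.31e-06, and adjusted p = 0.7 with an estimated correlation), with 13 of 14 negative and none that fell when adjusted over the list alone. The median of this list, −0.64, was −1.02 without IFNα 2 h replicate 3 and −0.09 without IFNα 2 h replicate 2. Fdft1, which makes squalene, had −0.66 ± 0.20 (adjusted p = 0.154), and Cyp51 had −0.80 ± 0.26 (adjusted p = 0.157). B cell identity genes were higher by 0.45 above all genes (camera adjusted p = 0.000881, and adjusted p = 0.758 with an estimated correlation), with 18 of 19 positive and 2 that rose when adjusted over the list alone. Their median log2 difference, 0.65, was 0.39 without IFNα 2 h replicate 3, and the adjusted p was 0.0934 with the interquartile range of each array as a covariate. The complement receptor Cr2 had 0.97 ± 0.23 (adjusted p = 0.141).

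Another 3 lists were higher at 8 h than at 2 h, with calls that single arrays ended. MHC class II genes lay 0.50 above all genes (camera adjusted p = 0.0114, and adjusted p = 0.758 with an estimated correlation), with all 11 positive and 2 that rose when adjusted over the list alone. The class II median, 0.70, was 0.20 without IFNα 2 h replicate 3, with an adjusted p of 0.175, and 1.19 without IFNα 2 h replicate 2. Interferon signalling genes lay 0.37 above all genes (camera adjusted p = 0.0227, and adjusted p = 0.863 with an estimated correlation), 5 rose when adjusted over the list alone, and Irf8 had 1.17 ± 0.22 (adjusted p = 0.141) and Irf7 1.49 ± 0.43 (adjusted p = 0.147). Their median, 0.57, was 0.23 without IFNα 2 h replicate 3 and 0.95 without IFNα 2 h replicate 2, with adjusted p of 0.27 without the former, 0.0597 without IFNα 8 h replicate 2 and 0.104 after quantile normalization. Irf9 had 0.37 ± 0.36 (adjusted p = 0.513), Socs1 −0.31 ± 0.21 (adjusted p = 0.379) and Myc 0.72 ± 0.24 (adjusted p = 0.167). Irf9 stood at −0.18 without IFNα 2 h replicate 3. Interferon-inducible GTPases lay 0.46 above all genes (camera adjusted p = 0.0486, and adjusted p = 0.758 with an estimated correlation), with all 6 positive, none past the threshold when adjusted over the list alone and Gbp9 at 0.77 ± 0.23 (adjusted p = 0.151). Their median, 0.67, was 0.30 without IFNα 2 h replicate 3 and 1.03 without IFNα 2 h replicate 2, and their adjusted p was 0.241 without the former, 0.0697 without either control array, 0.0607 without IFNα 8 h replicate 2 and 0.0828 after quantile normalization. With the interquartile range of each array as a covariate the adjusted p of these 3 lists was 0.649, 0.77 and 0.586, in the order given. After removal of the trend with signal level and gene span it was 0.00598, 0.116 and 0.0571, so the calls of interferon signalling and of the GTPases ended. Their medians against all genes went from 0.37 (SD over members 0.44) to 0.20 (SD 0.48) and from 0.46 (SD 0.0864) to 0.32 (SD 0.0844), and the 7 other lists that passed between 8 h and 2 h remained.

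For single genes between 2 h and 8 h of IFNα limma gave 0 higher and 0 lower, the smallest adjusted p was 0.141, and 2039 genes were higher and 253 lower at an unadjusted p under 0.05. The test recovered 58.2% of simulated changes of 1 and 100% of those of 2 or 3 on the log2 scale. Those simulated genes varied independently, and many were changed at once, which makes the adjustment easier. The simulation therefore does not show that no change of 2 was missed here. The counts were 4150 higher and 1276 lower without IFNα 2 h replicate 2 and 240 and 92 without IFNα 2 h replicate 3.

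The remaining 10 lists passed camera in none of the 3 comparisons as designed. In the list of MHC class I presentation the class I genes H2-K1, H2-D1 and H2-T23 had no probe set with a single symbol and are not analysed here. Its other genes lay at 0.06 and 0.32 relative to all genes at 2 h and 8 h against the control (camera adjusted p = 0.632 and 0.168), with the proteasome subunit Psmb10 at 0.99 ± 0.23 at 8 h (adjusted p = 0.169). Plasma cell differentiation genes lay at 0.01 and 0.33 (camera adjusted p = 0.967 and 0.0757, the latter 0.0246 after quantile normalization and 0.0447 with the replicate number as a block), with Cd93 at 0.98 ± 0.24 at 8 h (adjusted p = 0.183). The list of secretion and the unfolded protein response lay at −0.02 and −0.01 (camera adjusted p = 0.865 and 0.271), with Creld2, a protein of the endoplasmic reticulum, at 1.24 ± 0.21 at 8 h (adjusted p = 0.0882). Negative feedback genes lay at −0.05 and 0.11 (camera adjusted p = 0.865 and 0.426). At 2 h their median log2 difference was −0.10, their mean 0.12 and the direction of the test up. Genes of activation, costimulation and trafficking lay at 0.10 and 0.18 (camera adjusted p = 0.212 and 0.271), with Slfn2 at 1.54 ± 0.32 at 2 h (adjusted p = 0.309) and the costimulatory molecule Cd80 at 1.03 ± 0.24 at 8 h (adjusted p = 0.171). Genes of NF-kB and the immediate early response lay at 0.04 and 0.04 (camera adjusted p = 0.865 and 0.536), and G1/S and DNA replication genes at −0.11 and −0.05 (camera adjusted p = 0.967 and 0.511). Myc and ribosome biogenesis genes lay at −0.03 and −0.10 (camera adjusted p = 0.967 and 0.511), and glycolysis and hypoxia genes at −0.18 and −0.16 (camera adjusted p = 0.632 and 0.271). Genes of RNA and stress handling lay at 0.08 and 0.15 (camera adjusted p = 0.703 and 0.775). Between 8 h and 2 h of IFNα the adjusted p of these 10 lists ran from 0.109 to 0.888. With the interquartile range of each array as a covariate 4 of them passed as lower. At 8 h against the control the adjusted p was then 0.00191 for G1/S, 0.00208 for Myc and ribosome biogenesis, 0.00191 for NF-kB and 0.000406 for glycolysis, and at 8 h against 2 h it was 0.0013, 0.00121, 9.48e-05 and 0.00335. After removal of the trend with signal level and gene span, MHC class I presentation and plasma cell differentiation passed as higher at 8 h against the control (adjusted p = 0.0415 and 0.0223).

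Markers of other cell types were mostly dim. Of the 6 lists, T cell and macrophage markers had 3 tested members each and NK cell, dendritic cell, neutrophil and erythroid markers had 1 each, and none passed camera, with adjusted p from 0.168 to 0.953. At 8 h against the control the macrophage and monocyte list lay 0.60 above all genes (camera adjusted p = 0.168), 1 of its 3 members rose when adjusted over the list alone, and the list passed after removal of the trend with signal level and gene span (adjusted p = 0.0236, median 0.85 above all genes). The T cell list passed fry, with adjusted p of 0.0145 at 2 h against the control and 0.0099 at 8 h against 2 h. The brightest member of the T cell list, Cd2, had a mean log2 intensity of 9.68, above 89.5% of genes, and that of the dendritic cell list, Flt3, had 8.74. Such levels do not tell which cells expressed these genes. Cd68 of macrophages had 7.93, Slc4a1 of erythroid cells 7.64, Prf1 of NK cells 7.54 and Camp of neutrophils 7.39.

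The 2 h and 8 h comparisons share their control arrays. All 3 genes that rose at 2 h were among the 25 that rose at 8 h, where independent lists of those sizes would share 0.0071 genes and simulated unchanged groups shared 0.01 on average over 100 draws. Unchanged groups yield few calls, so their overlap was low in advance, and independent lists take no account of the shared controls. The low control values of these 3 genes enter both comparisons, so the overlap does not tell a shared response from shared controls. Across the 10533 genes, which are not independent replicates, the log2 differences of the 2 comparisons had a Pearson correlation of 0.283, and unchanged groups set against the same controls gave 0.499. The covariance was 0.0411 against a simulated 0.0352, a difference of 0.0059. The simulated genes varied independently, whereas the real arrays also differed in their signal range. The simulated values are therefore not the no-effect values of these arrays, and the difference is not read as a shared effect. The correlation was −0.03 without IFNα 2 h replicate 2 and 0.516 without IFNα 2 h replicate 3, and since 2 controls cannot be split, part of any excess may come from sharing them.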

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

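In this part the tests with the interquartile range of each array as a covariate, quantile normalization and the removal of the trend with signal level and gene span in lists other than the 3 patterns weighed were chosen only after results were seen. The 3 patterns weighed were themselves picked from the list tests on these data. Between 8 h and 2 h of IFNα 9 gene lists differed by camera with a preset correlation, and none of these calls held with an estimated correlation (adjusted p from 0.7 to 0.863). Without an 8 h control this is no measure of a difference in the effect of IFNα. After removal of that trend 7 of the 9 calls remained. It ended those of interferon signalling (adjusted p = 0.116, median against all genes from 0.37 to 0.20, SD over members 0.44 and 0.48) and of interferon-inducible GTPases (0.0571, from 0.46 to 0.32, SD 0.0864 and 0.0844), whose medians shrank.

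At 2 h against the control the removal ended 4 of 5 list calls. The median against all genes shrank for B cell identity (adjusted p = 0.12, from −0.32 to −0.09, SD 0.31 and 0.31, with the mean from −0.35 to −0.22), G2/M (0.2, from −0.21 to −0.11, SD 0.30 and 0.27) and cytokines (0.12, from 0.26 to 0.14, SD 0.56 and 0.53). For MHC class II (0.0769) it stayed near its size, from −0.49 to −0.41 (SD 0.40 and 0.41), so that lost call does not speak for the trend.

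Median log2 differences, 8 h minus 2 h, were 0.7556 for antiviral effectors, 0.6753 for nucleic acid sensors and 0.6664 for ubiquitin, ISGylation and PARP genes. They were 0.5737 for interferon signalling and regulatory factors, 0.6665 for interferon-inducible GTPases and 0.6999 for MHC class II presentation. These values hold the shift of the tested genes, whose median was 0.202. Against all genes they were 0.55, 0.47, 0.46, 0.37, 0.46 and 0.50 in the order given, and the medians after quantile normalization were 0.55, 0.35, 0.55, 0.23, 0.44 and 0.59. Without IFNα 2 h replicate 3 the medians of interferon signalling, the GTPases and MHC class II were 0.23, 0.30 and 0.20, and none of these 3 calls held (adjusted p = 0.27, 0.241 and 0.175).

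The G2/M list was higher at 8 h than at 2 h, with a median log2 difference of 0.6944, which was 0.49 against all genes. Its control arrays stood at a median log2 intensity of 9.83 and 10.12, its IFNα 2 h arrays at 9.69 and 9.48 and its IFNα 8 h arrays at 10.66 and 10.78. The narrow signal range of IFNα 2 h replicate 3 is argued against as the whole cause, since the adjusted p without that array was 6.93e-05, and so is a trend with signal level and gene span, since the adjusted p after its removal from each array was 3.99e-05, although the median against all genes shrank to 0.35 (SD over members 0.33 before and 0.30 after). The G1/S and DNA replication list did not rise with it (−0.03 against all genes, camera adjusted p = 0.715, and lower at 0.0013 with the interquartile range of each array as a covariate), so a rise in dividing cells is not shown. Longer culture and longer exposure may each account for the G2/M list, and without an 8 h control both stay open.

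The B cell identity list was higher at 8 h than at 2 h, with a median log2 difference of 0.6520, which was 0.45 against all genes both before and after removal of the trend with level and span. The mean against all genes did shrink with the removal, from 0.48 to 0.34. The list's IFNα 2 h arrays stood at 11.09 and 10.07, and its 4 other arrays between 11.13 and 11.65. The adjusted p was 0.0106 without IFNα 2 h replicate 3 and 0.00175 after that removal, which argues against each as the whole cause. With the interquartile range of each array as a covariate the adjusted p was 0.0934 and the median log2 difference 0.32, so a part that follows the signal range of the arrays stays open. No biological explanation was tested, and the lower level of this list at 2 h against the control did not pass after the removal (adjusted p = 0.12).

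The cholesterol synthesis list was lower at 8 h, with a median log2 difference of −0.6378 from 2 h. That size rests on IFNα 2 h replicate 2: without it the median was −0.09, and the 2 h arrays stood at 10.37 and 9.45 against 9.25 and 9.48 at 8 h. Both medians hold the shift of the tested genes, so how far the list's difference against all genes shrank without that array is not shown. The narrow array is argued against by an adjusted p of 2.09e-13 without it, and the trend with level and span by an adjusted p of 4.99e-11 against the control after its removal, with the median against all genes at −0.73 before and −0.84 after. The length of culture and IFNα cannot be told apart, because 0 of the 6 arrays used here stand for 8 h without interferon. Suppression of sterol synthesis by IFNα is therefore a hypothesis that may hold beside an effect of 6 more hours of culture.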

How the results depend on the processing

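Quantile normalization, the interquartile range (IQR) covariate and the crossed pairing were chosen only after results were seen. The counts of changed genes depended on the processing more than the direction of named genes did: for results on named genes, 2255 kept their direction and side of the threshold, 315 passed only under the alternative, 175 passed only as designed and 12 turned direction. For results on lists that passed, 213 stayed past the threshold and 73 did not. Where no reason is given, the cause was not tested. Signal over background limits the dim genes, 9219 of which were not tested.

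At 2 h against the control (3 higher, 0 lower), the number of higher genes was 5 with the stricter filter, 7 with a trended and robust variance, and 1 each with median centring, an offset of 32 and only the 2 groups compared, and Rtp4 remained past the threshold in each of these. With the IQR covariate it was 689 higher and 1180 lower. Leaving out 1 array gave 0 to 498 higher and 0 to 1517 lower. At 8 h against the control (25 higher, 1 lower), the counts were 6 higher and 0 lower with median centring, 11 and 0 with quantile normalization, 1228 and 105 with only the 2 groups compared and 542 and 628 with the IQR covariate. The lower count was 0 with no filter and with the offset and 2 with cyclic loess, where Mt2 was not among the lower genes. The share of higher calls thus went from 25 of 26 to 31 of 33 with cyclic loess and to all with both other scalings. Leaving out 1 array gave 0 to 1228 higher and 0 to 105 lower. Without either IFNα 2 h array the fit loses that group's disagreement between replicates, as it does with only the 2 groups compared. At 8 h against 2 h (0 and 0), the IQR covariate gave 430 and 336, and leaving out 1 array gave 0 to 4150 higher and 0 to 1276 lower. Of the 29 calls on named genes, median centring ended 22, quantile normalization 16, the offset 8, cyclic loess 6, no filter 5, a trended and robust variance and only the 2 groups compared 2 each, leaving out either control array 29 and leaving out either IFNα 8 h array 25.

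The number of lists that passed (5, 8 and 9 in the 3 comparisons) was 0, 0 and 0 with an estimated correlation, 1, 1 and 1 with fry, and 8, 16 and 14 with no filter, where more dim genes enter the background. Fry kept only 1 of the list calls, antiviral effectors at 8 h, and ended 21, since the list it passed at 2 h and at 8 h against 2 h was that of T cell markers, which camera had not called. Leaving out 1 array gave 3 to 7 lists at 2 h. After removal of the trend with signal level and gene span from each array 1, 8 and 7 of these calls remained, and 1, 3 and 0 other lists passed. The correlation between the 2 h and 8 h differences (0.283) was 0.467 with the IQR covariate and from −0.0277 (without IFNα 2 h replicate 2) to 0.516 when 1 array was left out.

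The direction of named genes turned in these cases. When 1 array was left out, the 2 h log2 difference ran from −0.0078 (without IFNα 2 h replicate 2) to 0.36 (without IFNα 2 h replicate 3) for Gbp9, from −0.12 to 1.08 for Dnajb1 and from −0.21 to 0.78 for Irf7, with the extremes from the same arrays. The median of the MHC class II list at 2 h, −0.54, was 0.0038 without IFNα 2 h replicate 3. With the IQR covariate the 8 h log2 difference was −0.14 for Dnajb1 and −0.13 for Socs1, and that of 8 h against 2 h was −0.076 for Traf1, −0.058 for Hk2, −0.089 for Mdm2, −0.41 for Irf9 and −0.079 for Usp18. Irf9 was also −0.043 with cyclic loess and ran from −0.18 (without IFNα 2 h replicate 3) to 0.93 (without IFNα 2 h replicate 2) when 1 array was left out. No list that passed turned the direction of its test with quantile normalization or the IQR covariate. Of the other lists 7 turned at 8 h against the control and 5 at 8 h against 2 h with the IQR covariate, MHC class II, B cell identity and secretion at 8 h among them, from higher to lower. With quantile normalization 4 turned at 2 h and 1 at 8 h against 2 h.

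Deviations of same-numbered arrays from the group means correlated at −0.430 between control and 2 h, −0.440 between control and 8 h and 0.570 between 2 h and 8 h, so the numbers went together between the IFNα groups and not with the control. With the number as a block, 7 genes were higher at 2 h, 22 higher and 1 lower at 8 h and none between 8 h and 2 h, and 4, 9 and 9 lists passed. The block ended 6 of the 29 calls on named genes: Parp14, Gpr183, Nmi, Gm4759, Slfn5 and Oasl2 at 8 h against the control (adjusted p from 0.0521 to 0.0673). Of the list calls it ended that of G2/M at 2 h alone (adjusted p = 0.056). Plasma cell differentiation passed with it at 8 h against the control (adjusted p = 0.0447). With the numbers of the controls exchanged, the counts were 39 higher and 7 lower at 2 h, 388 and 32 at 8 h and 1637 and 108 between 8 h and 2 h.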

Other observations

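The grouping by gene family, all tests on these families and the test on small RNAs were chosen only after results were seen. Genes were grouped by the letters before the number in their symbol into 447 families, which are sets of symbols and not of checked function, each tested with camera, and no family call held with an estimated correlation (adjusted p of 1 at 2 h and 0.996 at 8 h against the control, and 0.983 between 8 h and 2 h). In the 3 comparisons (2 h and 8 h against the control and 8 h against 2 h) 20, 27 and 29 families passed, and 15, 11 and 3 of them still passed in the same direction after removal of the trend with signal level and gene span. Between 8 h and 2 h the Mir family turned, from a median of −0.36 (camera adjusted p = 8.32e-15) to 0.21 after the removal (adjusted p = 0.0418). At 8 h against the control the smallest adjusted p belonged to families that lay lower without any single gene past the threshold. The 50 Olfr genes had a median log2 difference of −0.44, Col genes −0.37, Mir genes −0.40 and Krtap genes −0.56 (camera adjusted p = 1.95e-15, 6.05e-13, 2.43e-12 and 1.42e-08, and 4.53e-05, 6.36e-08, 0.171 and 0.000366 after removal of the trend). All 4 medians against all genes shrank with that removal, Olfr from −0.59 (SD over members 0.15) to −0.28 (SD 0.18), Col from −0.52 (SD 0.09) to −0.39 (SD 0.15), Mir from −0.54 (SD 0.50) to −0.13 (SD 0.54) and Krtap from −0.71 (SD 0.18) to −0.56 (SD 0.19). Krt and Vmn genes had −0.32 and −0.93 (camera adjusted p = 9.47e-05 and 0.000467). The median levels of Olfr (7.53), Krt (7.63) and Vmn (7.37) lay near the level cut of log2 7.45. Those of Col (7.90), Mir (8.08) and Krtap (8.47) lay higher. The lower quartile of all probe sets was 6.23 and 6.36 on the IFNα 8 h arrays, below the 6.59 and 6.49 of the controls. Signal near the cut is not shown to stand above background, so a fall in expression of Olfr, Krt and Vmn genes is not shown. Whether the signal of Col, Mir and Krtap genes stands above background was not tested, so a fall in their expression is not shown either. At 2 h symbols with Rpl were higher by 0.25, with Rps by 0.31 and with Mrps and Mrpl both by 0.26 (camera adjusted p = 1.94e-06, 1.85e-05, 2.15e-06 and 3.69e-05), and the Rps symbols include kinases such as Rps6ka3. Among other families, Ifi genes had 0.74 at 2 h and 1.52 at 8 h (camera adjusted p = 1.84e-07 and 4.7e-07). Schlafen genes (Slfn, 6 genes), which restrain proliferation and viruses, had 0.78 and 1.15 (camera adjusted p = 6.71e-05 and 0.000414), and 2 of them, Slfn5 and Slfn8, rose at 8 h. The 4 metallothionein genes, Mt2 among them, had −0.67 at 8 h (camera adjusted p = 0.000467). Against all genes their median went from −0.81 (SD over members 0.85) to −0.75 (SD 0.87) after removal of the trend, where the call ended (adjusted p = 0.051) though the difference shrank little. At 2 h the 7 Psma genes, subunits of the proteasome, had 0.55 (camera adjusted p = 0.0102).

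Small structured RNAs were higher at 2 h of IFNα than in the control. The 18 Snora genes had a median log2 difference of 1.46 and the 24 Snord genes 1.20 (camera adjusted p = 8.61e-18 and 4.95e-17). Over 46 small RNA genes (42 small nucleolar and 4 small nuclear), the arrays' medians were 10.08 and 9.11 in the control, 11.62 and 10.73 at 2 h and 9.81 and 9.86 at 8 h. As median deviations from each gene's mean, the arrays stood at −0.14 and −1.02 in the control and at 1.17 and 0.29 at 2 h. On that measure the gap between the 2 replicates was 0.878 in the control and 0.882 at 2 h. The larger gap was 0.6756 of the 1.31 between the group means. Differences between single arrays in the recovery of small RNAs may therefore produce such a change, and with 2 arrays per group this and a response to IFNα cannot be told apart.

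Among 2119 bright probe sets that named several genes or none, limma called 0 in each comparison, with 146, 175 and 254 at an unadjusted p under 0.05 for 2 h against the control, 8 h against the control and 8 h against 2 h. The first principal component held 60.7% of the variance and placed IFNα 2 h replicate 3 at 48.2, with the other 5 arrays between −33.0 and 17.8. The log2 differences of single genes followed their signal level, with Spearman correlations across genes, which are not independent replicates, of −0.23, 0.31 and 0.42 in the 3 comparisons. After removal of this trend and that with gene span from each array, 3 genes were higher at 2 h, 25 at 8 h and 0 between 8 h and 2 h, with none lower, and 2 and 16 of the genes called before remained.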
